A study of Drosophila melanogaster with 48 samples.

How the data were processed

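RNA was sequenced from the abdominal fat body of mated female flies of the w1118 strain. The dissected tissue included oenocytes and epidermis, and intestine, ovaries and Malpighian tubules had been cut away, per the labels' protocols. Flies of about 3 days were kept for 5 days on a control diet with 15% sucrose and yeast or on a restricted diet with 5%, at 25 °C with 12 h of light and 12 h of dark. Tissue was collected every 2 h at 12 zeitgeber times (ZT, hours after lights on), from about 10 flies per library. Each of the 24 combinations of diet and time had 2 libraries, so that 48 libraries entered the comparisons. The submitters' design text calls the replicates biological. It does not say whether flies of the same replicate number shared a cage, day or library batch.

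The authors deposited a table of estimated counts per gene and a table of TPM (transcript abundance scaled to a fixed library total) per gene. The submitters' processing notes name kallisto 0.44.0, which assigns reads to transcripts without a genome alignment, and FastQC. The transcript annotation, the genome build and the step from transcripts to genes are not given in the sources used here, so no coordinates are printed. Whether the reads kept strand is likewise not given in the sources used here, so overlapping and antisense genes could not be told apart by strand. Of the deposited estimated counts, 88.2% were whole within 0.01, and they were rounded to whole numbers. Both tables had 14205 gene rows, of which 14051 had a symbol in the name table and 154 had none. Near-identical rows, such as the 23 rows of ribosomal RNA, share reads that an estimated count can divide between them, and their single values are uncertain. All 23 ribosomal RNA rows and 13 rows of mitochondrial genes stayed in the library sizes.

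The samples, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. Genes were kept with filterByExpr at a minimum count of 10 over the groups of diet and time, which left 10070 genes, 131 of them without a symbol. Library sizes were scaled with TMM, and genes were tested with edgeR 4.0.16 (quasi-likelihood F test, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05) in R 4.3.3. The diet effect was tested with time as a factor, as restricted minus control. Rhythms were tested with a cosine and a sine of 24 h for each diet in a joint fit. The rhythm difference tested whether these terms differed between diets. Amplitudes are the distance from the mean to the peak of the fitted curve on the log2 scale. Those printed with a standard error come from a least-squares fit of the same curve to log2 CPM (prior count 2), and all adjusted p-values come from edgeR. The amplitude ratio is the median log2 ratio, restricted over control, over genes rhythmic on average. The phase shift is the median difference in peak time over genes rhythmic in both diets and on average. Both were compared with 100 permutations of the diet labels within each time.

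A total of 33 lists of pathways, complexes and cell type markers was drawn up, with 503 members asked for by name and 463 found, and 32 lists had at least 3 tested members. The list of spermatheca and sperm markers had fewer and was not tested. Diet changes of lists were tested with camera (limma 3.58.1), with a preset correlation between genes of 0.01 and again with an estimated correlation. The share of rhythmic genes in a list was tested with Fisher's exact test. Both were adjusted over the 32 lists. The rule for named genes took the 10 highest and 10 lowest diet changes with an adjusted p under 0.05, a mean of at least 10 CPM and the same direction at 10 or more of the 12 times. It also took all core clock genes, the 10 largest amplitudes per diet with an adjusted p under 0.05 and at least 10 CPM, up to 12 genes with a rhythm difference (the 3 smallest p where none passed at 10 CPM), and up to 4 members of each list with the smallest p. Genes without a symbol were counted and not named.

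The mean log2 CPM of the ovary list and of the gut list served as marker scores of each library. Their use as covariates, the removal of ribosomal RNA and mitochondrial rows and the removal of 1 library rich in ribosomal RNA were chosen after seeing the data. The alternatives fixed earlier were DESeq2 1.42.0 as test and for size factors, no filter, a replicate block, each replicate series alone, each library left out in turn, limma on log2(TPM + 1), limma on log2 CPM, an estimated gene correlation for the lists, the 20 most abundant genes left out of the library size, a time factor in place of the cosine, no time term, and a minimum fold of 1.5. The leave-one-out fits were first run with the low-count filter repeated for each set of 47 libraries. After those counts were seen the 10070 genes were held fixed, so that a single choice changes, and both versions are given.

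The steps were tested on simulated counts with known changes in 9871 genes. For the diet effect 75.5% of genes changed by 1.5-fold and 89.4% of those changed by 2-fold were recovered. For the control rhythm 50.0% of amplitudes of 0.5 and 87.8% of amplitudes of 1 were recovered, and for the rhythm difference 53.1% and 74.0%. False calls numbered 4 of 9677 unchanged genes for the diet effect, and 10 and 9 of 9673 for the control rhythm and the rhythm difference. Each gene was simulated independently, without variation that many genes share, such as differing amounts of ovary or gut RNA. The simulated rates may therefore not hold for the real libraries. No pair of libraries held identical columns. The 2 libraries of a group had a median correlation of 0.937 (0.893 to 0.967) across genes, which are not independent replicates.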

Results

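The transcriptome of the abdominal fat body was followed over a day in flies on a control or a restricted diet, with 24 libraries per diet and 2 at each of 12 times. Total estimated counts per library ranged from 5815484 to 33485917. The most abundant transcripts were those of the oenocyte enzyme Cyp4g1 (6.02% of counts on average) and of the yolk proteins Yp1 (5.03%), Yp2 (3.33%) and Yp3 (3.03%). Transcripts of tissues that the dissection removed were present in varying amounts. The mean log2 CPM of ovary markers correlated with the first principal component (25.4% of the variance, Pearson r = -0.94, Spearman rho = -0.89, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). That of gut markers correlated with the second (17.6%, r = 0.92, rho = 0.83, permutation p = 1e-05 for each). Without the 2 libraries farthest from the median r was -0.92 and 0.89, and both p adjusted over these 2 relations were 1e-05. Within the replicate 1 libraries r was -0.90 (ovary) and 0.96 (gut), and within the replicate 2 libraries -0.92 and 0.87 (24 libraries each, permutation p = 1e-05 for each, also after adjustment).

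**Figure D1:**
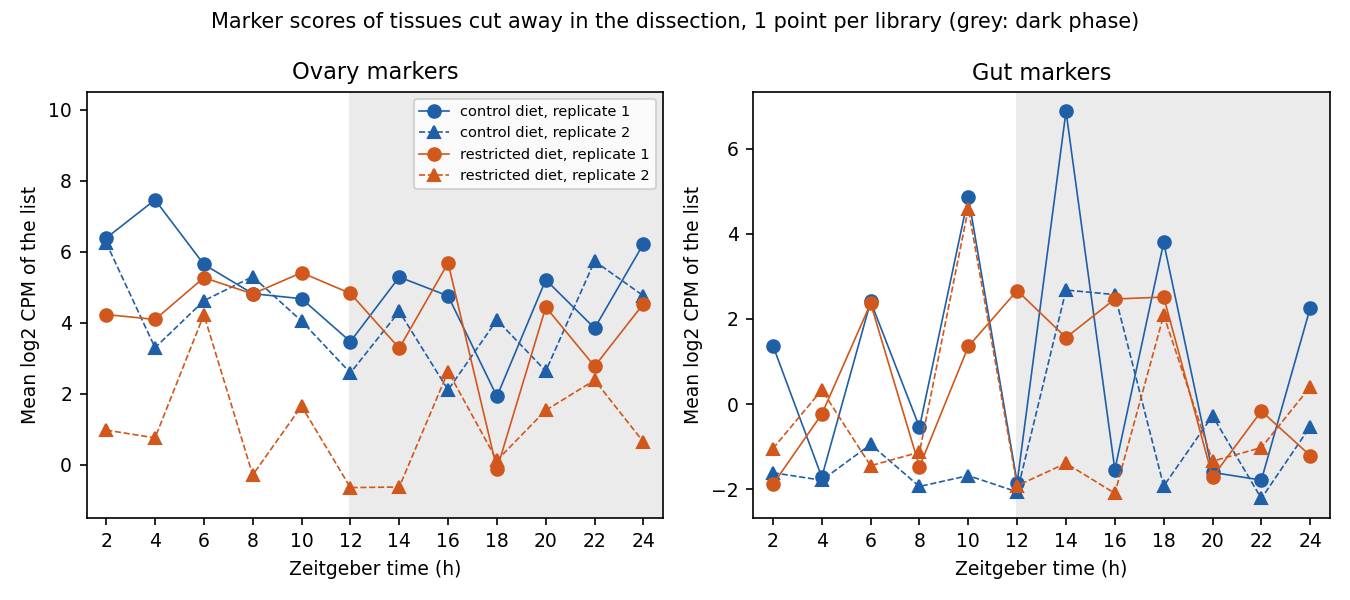
Mean log2 CPM of the ovary list (left) and of the gut list (right) against zeitgeber time in h, 1 point per library, with lines joining the libraries of one diet and replicate series and the dark phase in grey. Ovary scores were lowest in the restricted replicate 2 series (mean 1.11, against 4.14 in the control series of the same number), and gut scores peaked in single libraries of both diets.

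On the restricted diet eggshell and germline transcripts were lower, and many other genes were lower or modestly higher. Of 10070 genes tested, 1048 were higher and 1553 lower on the restricted diet (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 24 libraries per diet), and 554 of these 2601 differed by at least 1.5-fold. On log2(TPM + 1), where the median of all genes shifted by -0.10 relative to the edgeR fit, limma called 309 higher and 1599 lower. Among the 10 lowest genes, the vitelline membrane genes Vm26Ab, Vm26Aa, Vm34Ca and Vm32E and the chorion gene Cp19 encode parts of the eggshell. Vm26Aa (FBgn0003979) averaged 256 ± 200 CPM (SD, n = 24) on the control diet and 71.0 ± 125 on the restricted diet, a log2 change of -2.62 ± 0.82 (SE, edgeR adjusted p = 0.0216). Cp19 (FBgn0000358) changed by -4.21 ± 1.27 (edgeR adjusted p = 0.0186) and Vm32E (FBgn0014076) by -3.42 ± 0.98 (edgeR adjusted p = 0.0149).

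The remaining genes of the lowest 10 were of different kinds. The eggshell gene psd and ndl, a protease gene of ovarian follicle cells, changed by -2.06 ± 0.66 and -1.45 ± 0.54, and CG14309 by -4.36 ± 1.40. Lsp2 (FBgn0002565), which encodes a storage protein, and Gnmt (FBgn0038074), an enzyme that uses S-adenosylmethionine, changed by -2.13 ± 0.81 and -1.96 ± 0.68. The direction of both differed between the replicate series: Lsp2 changed by 1.30 in replicate 1 (edgeR adjusted p = 0.431) and by -6.56 in replicate 2 (adjusted p = 5.9e-05), and Gnmt by 1.90 (adjusted p = 0.244) and -4.60 (adjusted p = 0.00055).

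The 10 highest genes were led by phu (FBgn0043791, log2 change 2.01 ± 0.43, edgeR adjusted p = 0.00332, with 0.58 in replicate 1 and 2.50 in replicate 2), fmt (FBgn0035688, 1.78 ± 0.38, adjusted p = 0.00352) and Syt1 (FBgn0004242, 1.76 ± 0.24, adjusted p = 1.9e-05), which encodes the calcium sensor of synaptic vesicles. Syt1 averaged 4.33 ± 1.90 CPM on the control diet and 16.5 ± 12.2 on the restricted diet (SD, n = 24), and was higher at 12 of 12 times. BomS2, an immune-induced peptide gene, rose by 0.96 ± 0.20 (adjusted p = 0.00263). With the ovary and gut scores as covariates phu changed by 0.55 ± 0.41 (edgeR adjusted p = 0.543) and BomS2 by 0.37 (adjusted p = 0.337). The other 6 were ribosomal RNA pseudogene rows, with log2 changes from 1.44 to 1.57 and adjusted p from 0.0233 to 0.0356. Ribosomal RNA rows held a median of 1.11% of counts in restricted libraries and 0.375% in control libraries, and 53.8% in 1 restricted library (ZT 2, replicate 1).

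These calls rested mostly on the replicate 2 series. Tested within replicate 1 alone, 2 genes passed (1731 at an unadjusted p under 0.05), and within replicate 2 alone 4334 passed. Those 2, CG8112 and Alp2, named after their values were seen, changed by -0.90 and 1.88 in replicate 1. In replicate 2 CG8112 changed in the opposite direction (0.95, edgeR adjusted p = 5.9e-05), and Alp2 had a value of -0.53 (adjusted p = 0.558). The fold changes of both series had the same sign for 66.0% of 9711 genes (Pearson r = 0.23 across genes, which are not independent). For the genes called with all libraries, which were chosen on both series, this was 97.8%, with a median size of 0.25 in replicate 1 and 0.48 in replicate 2 (log2). The 2 series also differed in the mitochondrial share of counts, 5.67% and 2.30% on the control diet and 4.15% and 2.56% on the restricted diet. The main fits had no replicate term, so a difference between the series stayed in their spread. With a replicate block, an alternative fixed earlier, 1611 genes were higher and 2213 lower. The ovary score was lower on the restricted diet by -3.03 in replicate 2 (1.11 against 4.14, 12 libraries per diet, two-sided permutation test, p = 8e-05) and by -0.87 in replicate 1 (4.10 against 4.97, p = 0.175). Each test treats the 12 libraries of a series and diet as independent, and whether they shared a cage or day is not given. With the ovary and gut scores as covariates, a setting chosen after seeing the data, 26 genes passed, 24 higher and 2 lower, of which 14 were among the 2601. Among the 14 were Syt1 (1.74 ± 0.27, edgeR adjusted p = 0.000598), fmt (1.87 ± 0.42, adjusted p = 0.0448) and the P450 gene Cyp12e1 (0.43 ± 0.09, adjusted p = 0.0342). Adhr (0.58 ± 0.10, adjusted p = 0.00156) and BckdhB of branched-chain amino acid breakdown (0.28 ± 0.05, adjusted p = 0.00214), chosen after their values were seen, were also among them. The other 12 included the eggshell genes yellow-g2 (4.44 ± 0.74, edgeR adjusted p = 0.00123) and yellow-g (2.69 ± 0.62, adjusted p = 0.0448), chosen after their values were seen, which had values of 1.82 and 0.90 without the scores (adjusted p = 0.210 and 0.355), so that this fit was not taken as a corrected diet effect.

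Markers of cell types moved with the diet as well. Of 25 ovary markers 13 were lower and 0 higher (15 lower adjusted over the list alone), with a median log2 change of -1.18, and the germline genes otu, vas and bcd, chosen after their values were seen, changed by -1.22, -1.03 and -1.18. Higher markers numbered 6 of 10 for oenocytes (6 adjusted over the list alone, eloF 0.42 ± 0.10, with Hnf4 and Desat1 also in the lipid lists), 5 of 18 for epidermis and cuticle (5, Ddc 0.35 ± 0.08), 8 of 23 for muscle (9, with 1 lower, Mlc1 0.45 ± 0.12), 3 of 14 for hemocytes (3, Hml 0.44 ± 0.13) and 3 of 10 for neurons (3, led by Syt1). These 6 lists passed camera at the preset correlation. With an estimated correlation none did, with p = 0.0904 for ovary, 0.105 for oenocytes, 0.121 for epidermis and cuticle, 0.255 for muscle, 0.133 for hemocytes and 0.0957 for neurons. With the ovary and gut scores as covariates 1 gene of the 5 higher lists was called, Syt1. Their medians then fell from 0.26 to 0.09 for oenocytes, from 0.35 to 0.03 for epidermis and cuticle, from 0.23 to 0.02 for muscle, from 0.29 to -0.03 for hemocytes and from 0.55 to 0.34 for neurons, and of these lists camera called the neurons alone (adjusted p = 0.00187, and p = 0.106 with an estimated correlation). Of the 12 fat body markers 1 was higher (AkhR, 0.27 ± 0.09) and 1 lower (Lsp2), and 0 were called when adjusted over the list alone. Of 29 gut markers 1 was lower (Jon99Fii, 0 adjusted over the list alone), and of 9 Malpighian tubule markers 0 were called by either adjustment. These 3 lists did not pass camera. The medians of the gut and tubule lists had opposite signs in the replicate series, -1.42 and 1.16 for gut and 0.77 and -0.76 for tubule.

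Genes of lipid and energy metabolism were among those higher on the restricted diet, though not with the ovary and gut scores as covariates. Of 19 lipid synthesis genes 5 rose and 0 fell (6 rose adjusted over the list alone), among them the acyltransferase genes Gpat4 (0.22 ± 0.05), mdy (0.34 ± 0.08) and Agpat3 (0.26 ± 0.06) and the desaturase gene Desat1 (0.29 ± 0.09). Of 19 lipid breakdown genes 3 rose (3 adjusted over the list alone): Hnf4 (0.27 ± 0.06), the carnitine palmitoyltransferase gene whd (0.23 ± 0.08) and the adipokinetic hormone receptor gene AkhR. In glycolysis and sugar storage 3 of 21 rose (1 adjusted over the list alone), namely the trehalose transporter gene Tret1-1 (0.32 ± 0.09), Hex-C (0.40 ± 0.14) and Ldh (0.38 ± 0.14). In oxidative phosphorylation 13 of 67 rose (11 adjusted over the list alone), led by UQCR-11 (0.41 ± 0.07) and ND-MLRQ (0.38 ± 0.07). These 4 lists passed camera at the preset correlation and not with an estimated correlation (p = 0.234, 0.287, 0.351 and 0.298). With the ovary and gut scores 0 members of these 4 lists were called. The medians of lipid synthesis and lipid breakdown then fell from 0.18 to 0.01 and from 0.16 to 0.02, and that of oxidative phosphorylation from 0.26 to -0.11, where camera at the preset correlation called it lower (adjusted p = 0.00252, and p = 0.496 with an estimated correlation). The medians of glycolysis and proteasome also turned with these scores, to -0.09 and -0.03.

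Among lists of protein and RNA turnover, 6 of 33 proteasome genes rose (3 adjusted over the list alone, Rpn6 0.16 ± 0.05) and 6 of 21 ribosome biogenesis genes fell (9 adjusted over the list alone, Nnp-1 -0.37 ± 0.11 and pit -0.30 ± 0.10). Both passed camera at the preset correlation, with p = 0.319 and 0.228 with an estimated correlation. The proteasome median was -0.03 in replicate 1 and 0.28 in replicate 2, and that of ribosome biogenesis -0.16 and -0.27. Of 81 cytosolic ribosomal protein genes 1 fell and 0 rose (0 by adjustment over the list alone), and their median was -0.23 in replicate 1 and 0.38 in replicate 2. Of 71 mitochondrial ribosomal genes 1 rose and 2 fell, and of 21 endoplasmic reticulum genes 3 rose (0 in both lists adjusted over the list alone). Of 15 nucleotide synthesis genes 2 rose and 5 fell (3 and 7 adjusted over the list alone), the latter including the ribonucleotide reductase genes RnrL (-0.92 ± 0.30) and RnrS (-0.74 ± 0.25). These 4 lists did not pass camera. With the ovary and gut scores camera at the preset correlation called the cytosolic and mitochondrial ribosome lower (medians -0.22 and -0.09, adjusted p = 6e-25 and 2.6e-06, and p = 0.0632 and 0.280 with an estimated correlation).

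Defence genes were mixed. Of 70 P450 genes 14 rose and 3 fell (the same counts adjusted over the list alone), led by Cyp12e1 (0.58 ± 0.09) and Cyp9b1 (0.62 ± 0.13), and the list passed camera at the preset correlation (p = 0.223 with an estimated correlation). Of 55 glutathione and UDP transferases 6 rose and 3 fell (6 and 3 adjusted over the list alone). Of 40 humoral immunity genes 7 rose (6 adjusted over the list alone), including the bomanin genes BomT2 (0.72 ± 0.13), BomS2 and BomS3 (0.77 ± 0.17). Among 19 heat shock genes 3 fell (1 adjusted over the list alone), led by Hsp26 (-1.24 ± 0.35). Of 21 genes of oxidative stress defence 2 rose and 2 fell (1 and 2 adjusted over the list alone). Of 26 genes of amino acid and one-carbon metabolism 8 rose and 6 fell (8 and 6 adjusted over the list alone), among them AhcyL2 (0.56 ± 0.11) and the transsulfuration genes Cbs (-0.60 ± 0.16) and Cth (-0.27 ± 0.06). Of 24 insulin and TOR signalling genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), led by Pi3K21B (-0.49 ± 0.14). Of 20 autophagy genes 1 rose (0 adjusted over the list alone). Of 11 clock kinases and regulators tws (-0.40 ± 0.12) and dco (-0.29 ± 0.09) fell (2 adjusted over the list alone). None of the 3 yolk protein genes, 19 genes of gluconeogenesis and sugar response or 4 known clock outputs passed under either adjustment, and of the lists in this group camera at the preset correlation called the P450 genes alone. With the ovary and gut scores it called the P450 genes and the transferases higher (adjusted p = 0.0165 and 0.00908) and the heat shock and yolk protein genes lower (adjusted p = 0.0117 and 0.0327), with p = 0.345, 0.166, 0.216 and 0.126 with an estimated correlation. The median and mean differed in sign for humoral immunity (0.05 and -0.11) and fat body markers (0.05 and -0.23), and camera put the tubule list lower at a median of 0.32.

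**Figure D2:**
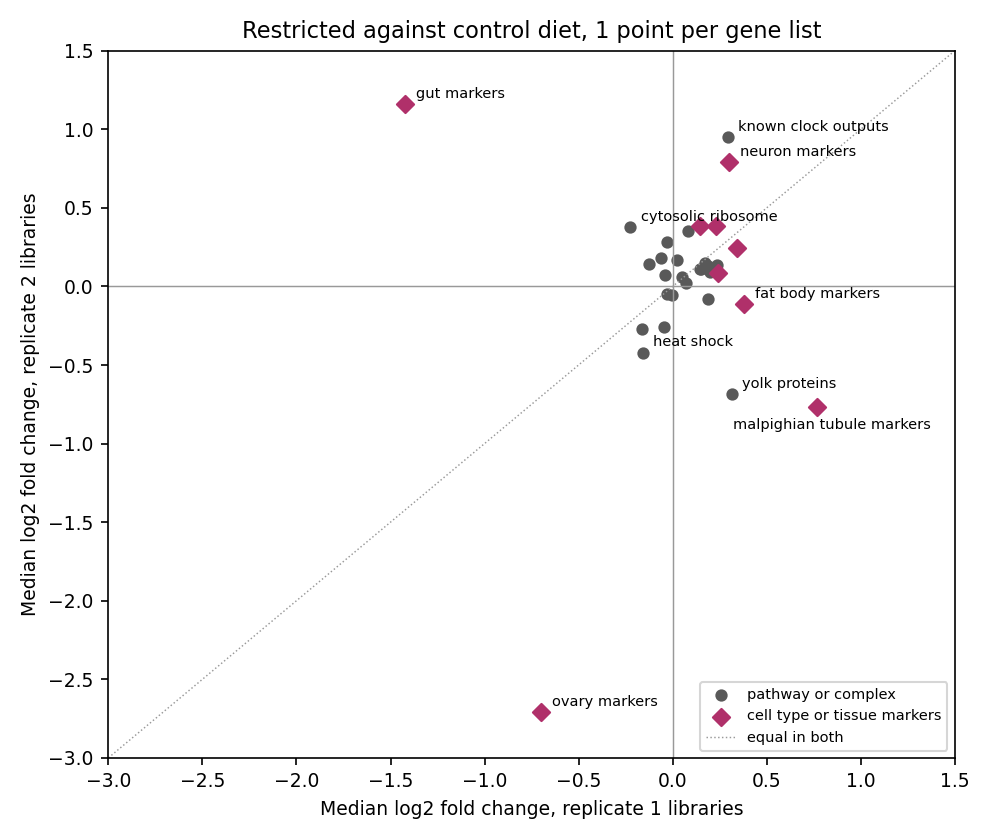
Median log2 fold change (restricted minus control) of each of the 32 gene lists in the replicate 1 libraries (horizontal axis) and in the replicate 2 libraries (vertical axis), with diamonds for marker lists, circles for pathways and complexes, and a dotted line of equality. The ovary list lay at -0.70 and -2.71 and the gut list at -1.42 and 1.16, while most pathways lay near 0 in both.

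Daily rhythms were next compared within each diet, which addresses the question in the study's title of how restriction affects the output of a peripheral clock. The core clock cycled in both diets. The light-responsive clock gene tim (FBgn0014396) had an amplitude of 1.48 ± 0.15 (SE, n = 24 libraries) on the control diet with a peak at ZT 17.4, and of 1.58 ± 0.15 on the restricted diet with a peak at ZT 17.8 (edgeR adjusted p = 1.2e-06 and 2.1e-08). Its partner per (FBgn0003068) reached 0.72 ± 0.12 and 0.78 ± 0.12 with peaks at ZT 15.6 and 15.5. The repressor gene vri (FBgn0016076) reached 1.12 ± 0.10 and 1.09 ± 0.10 with peaks at ZT 15.6 and 15.1, and the activator gene Pdp1 (FBgn0016694) 0.58 ± 0.09 and 0.43 ± 0.09. The activator Clk (FBgn0023076) ran in the opposite phase, with peaks at ZT 4.29 and 4.80 and amplitudes of 0.48 ± 0.10 and 0.72 ± 0.10. The photoreceptor gene cry (FBgn0025680) had amplitudes of 0.48 ± 0.12 and 0.71 ± 0.12 (edgeR adjusted p = 0.0516 and 0.00125, and 0.00970 on the control diet with both marker scores), while its difference between diets did not pass (adjusted p = 1.00). In level, 2 of the 8 core clock genes were higher on the restricted diet, cwo (0.17 ± 0.05) and Pdp1 (0.32 ± 0.09), and 1 was lower, cyc (-0.14 ± 0.05), with the same counts adjusted over the list alone and no call by camera. With both marker scores these changes were 0.17 ± 0.06 for cwo, 0.20 ± 0.10 for Pdp1 and -0.13 ± 0.05 for cyc and did not pass (edgeR adjusted p = 0.220, 0.368 and 0.265), though those of cwo and cyc kept their size. The repressor gene cwo had small rhythms in both (0.20 ± 0.04 and 0.22 ± 0.04). With both scores its fitted control amplitude stayed at 0.20 and the restricted one of Pdp1 went from 0.43 to 0.40, but neither passed (edgeR adjusted p = 0.112 and 0.0532). The gene cyc passed in neither (0.05 ± 0.04 and 0.06 ± 0.04, adjusted p = 0.798 and 0.983).

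**Figure D3:**
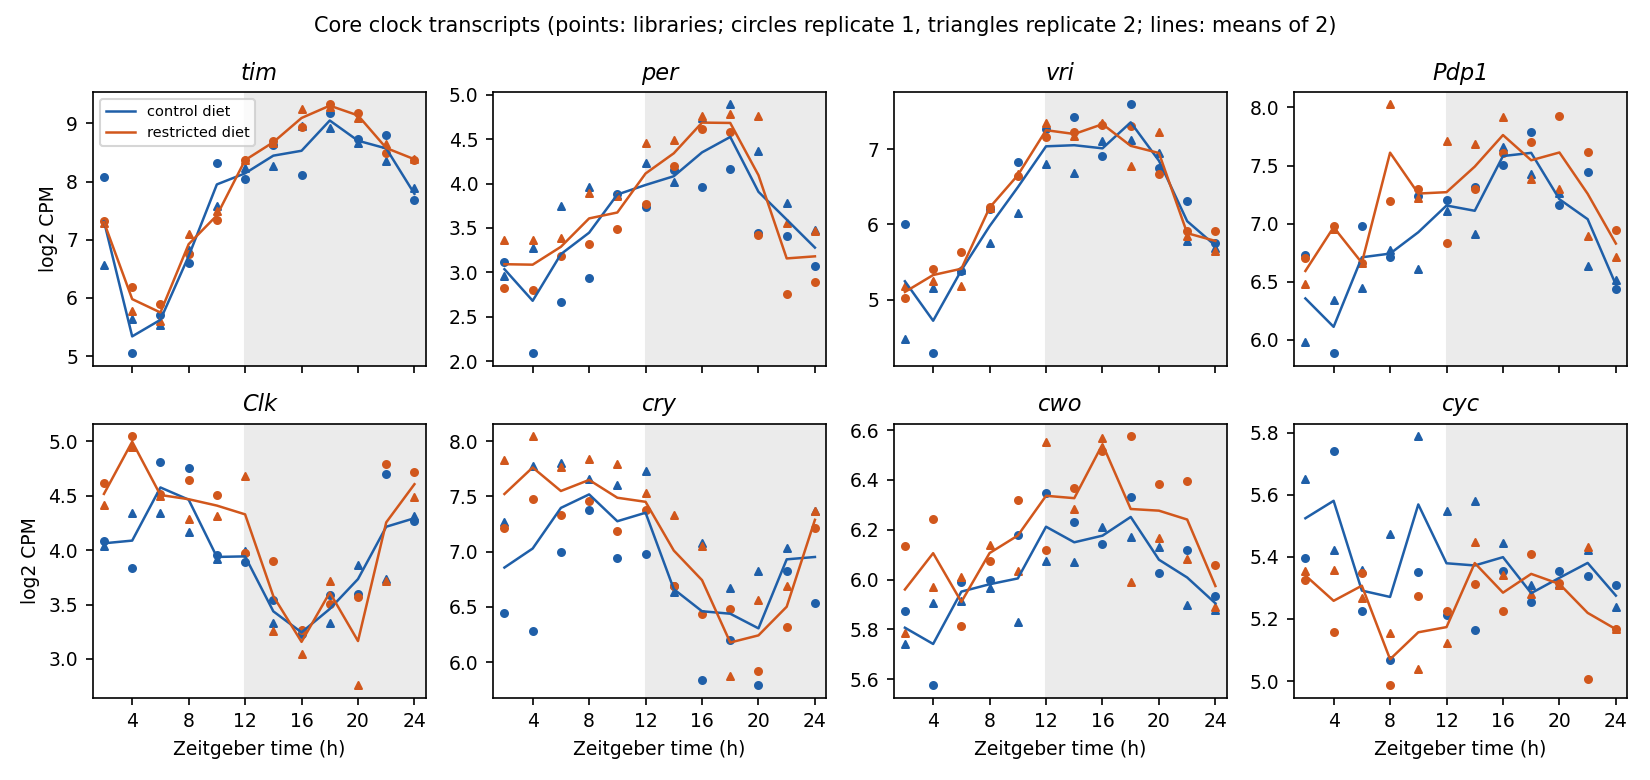
Expression (log2 CPM) of the 8 core clock genes against zeitgeber time in h, with circles for replicate 1, triangles for replicate 2, lines for the mean of the 2 libraries, blue for the control and orange for the restricted diet, and the dark phase in grey. In both diets tim rose to a peak near ZT 18, and Clk was highest in the light phase.

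Outside the clock, the genes with the largest amplitudes that passed in both diets at a mean of at least 10 CPM included the fatty acyl-CoA reductase genes CG17560 and CG17562 and geko. CG17560 (FBgn0038450) had amplitudes of 1.00 ± 0.10 on the control diet and 1.12 ± 0.10 on the restricted diet (SE, n = 24 libraries), with peaks at ZT 4.85 and 4.97. CG17562 (FBgn0038449) had 0.83 ± 0.10 and 0.98 ± 0.10, and geko (FBgn0020300) 0.89 ± 0.11 and 1.10 ± 0.11 with peaks at ZT 0.815 and 1.03. CG10096, also a fatty acyl-CoA reductase gene, had 0.84 ± 0.16 and 1.21 ± 0.16, and CG15021 0.84 ± 0.20 and 0.81 ± 0.20. CG40486 passed on the control diet (0.95 ± 0.22) and not on the restricted diet (0.76 ± 0.22, edgeR adjusted p = 0.132). The 3 largest fitted control amplitudes among genes that passed at a mean of at least 10 CPM, those of the chorion gene Cp7Fa, the photoreceptor gene Arr1 and CG34220, had large errors on the log2 CPM scale (2.68 ± 0.66, 0.13 ± 0.68 and 1.65 ± 0.51). On the restricted diet 7 of the 10 largest fitted amplitudes at that level were ribosomal RNA pseudogene rows that peaked near ZT 2, the time of the library with 53.8% ribosomal RNA.

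In all, 135 genes were rhythmic on the control diet and 116 on the restricted diet (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Both diets shared 44 of them, against 1.56 for independent lists. With the times redrawn within each diet and replicate, a median of 17 genes passed on the control and 24 on the restricted diet. On the control diet 68 of the 135 peaked between ZT 12 and 18, and on the restricted diet 32 of the 116 did, a contrast that was not tested. Rhythmic genes were enriched among the core clock, with 6 of 8 on the control and 7 of 8 on the restricted diet (7 and 7 adjusted over the list alone, Fisher's exact test, adjusted p = 3.5e-10), and among gut markers, with 3 and 1 of 29 (15 and 16 adjusted over the list alone, adjusted p = 0.0440), though genes of a list are not independent. No 24 h curve was detected in the gut score, the mean of these markers (permutation test, p = 0.347 in control and 0.254 in restricted libraries). With both marker scores as covariates the gut counts were 0 and 3. The gut score is built from these same genes, so that fit cannot test their rhythms. The gut genes called without the scores were zetaTry, iotaTry and LManVI on the control diet and thetaTry on the restricted diet, each at a mean below 10 CPM. Few genes of the other lists passed: on the control diet 2 genes of amino acid metabolism, 2 transferases, 1 P450 gene and the autophagy kinase gene Atg1, and on the restricted diet 1 or 2 genes in each of 9 lists. Adjusted over the list alone, the control counts of these 4 lists were 2, 4, 1 and 2, with 18 of 40 for humoral immunity (2 without the control library of ZT 14, replicate 1) and 3 for insulin and TOR signalling, and the largest restricted counts outside the clock and gut lists were 6 for gluconeogenesis and sugar response and 4 each for oxidative stress defence and P450 genes. The control count fell to 78 without the control library of ZT 14, replicate 1, and to 57 with the ovary and gut scores as covariates, 48 of them among the 135, while the restricted count was 128 with these scores, 77 of them among the 116, so that the order of the diets turned. Within replicate 1 alone 11 and 34 genes passed on the control and restricted diet, and within replicate 2 alone 20 and 75. The ovary score itself followed a 24 h curve in the control libraries, with an amplitude of 1.17 and a peak at ZT 3.30 (permutation test, p = 0.0062, adjusted over 4 tests 0.0248), while in the restricted libraries its p was 0.391.

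The rhythms of the 2 diets were compared by a test of the difference itself, and few genes passed. Of the 163 genes rhythmic in one diet only, 2 passed that test, and no core clock gene did (edgeR adjusted p = 1.00 for each of the 8). For tim the amplitude was larger on the restricted diet by 0.09 (95% interval -0.33 to 0.52), for Clk by 0.24 (-0.05 to 0.53), for cry by 0.23 (-0.11 to 0.58) and for vri by -0.02 (-0.30 to 0.25). Over all genes 2 passed (305 at an unadjusted p under 0.05), CG31265 and CG31077, both below 1 CPM on average and named here after their values were seen. DESeq2 called 7 genes, the fit with both marker scores 16, and limma on log2 CPM 0 (113 at an unadjusted p under 0.05). Each of the 16 averaged below 10 CPM, with the gut marker thetaTry highest at 9.92. The 3 smallest p among genes of at least 10 CPM belonged to ribosomal RNA pseudogene rows (adjusted p = 0.103 for each), and reached an adjusted p of 1.00 without the library with 53.8% ribosomal RNA.

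No difference in amplitude or peak time between the diets was detected over sets of rhythmic genes. Over 450 genes rhythmic on average the median log2 ratio of amplitudes, restricted over control, was -0.05 (quartiles -0.44 and 0.37), and 210 genes had the larger amplitude on the restricted diet. By least squares the median ratio was -0.01 (permutation test, two-sided, p = 0.950, 100 draws with an SD of 0.19). The ratio was 0.22 within replicate 2 and 0.15 within replicate 1, and 0.19 with the ovary and gut scores as covariates, so that its sign was not fixed by these data. Over the 8 core clock genes the median log2 ratio was 0.16 (0.13 by least squares, permutation p = 0.356). Over 43 genes rhythmic in both diets and on average the median peak time on the restricted diet differed by -0.21 h (quartiles -0.62 and 0.52 h). By least squares that median difference was -0.17 h (permutation test, two-sided, p = 0.515). Over the 6 clock genes rhythmic in both the median difference was 0.10 h (-0.00811 h by least squares, permutation p = 0.980).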

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

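The tests of the eggshell and germline genes and of the count without ribosomal RNA rows, and the fits with marker scores, were chosen only after the result was seen. The rhythm of 2 genes differed between the diets, CG31265 (edgeR adjusted p = 0.0250) and CG31077 (adjusted p = 0.0399). They had 0 counts in 37 and 38 of the 48 libraries and highest counts of 181 and 208 in single libraries, at ZT 2 of the restricted and ZT 10 of the control diet. Of 80 splits of the diet labels within times, the real one included, 58 gave at least 2 genes and 1 gave 478. Chance was therefore not excluded for this count, and why 1 split gave 478 was not tested. When each library was left out in turn, 28 of 48 moved the count by over 1.5 times, from 0 without the control library of ZT 14, replicate 1, to 16 without the restricted library of ZT 12, replicate 2.

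The other counts were compared with regrouped samples as well. The diet count of 2601 was reached by 1 of 80 splits, the real one, and the highest other split gave 721. That split had an ovary score difference of -1.96, against -1.95 for the real one. Labels were redrawn library by library within each time, so a random assignment of single libraries is an unlikely source of the count. A difference by chance that a whole series shared is not covered by these splits, and most calls rested on replicate 2. For the rhythms, orders of the times were redrawn within each diet and replicate. Of 100 orders, the real one included, 4 gave as many as 135 genes for the control rhythm, with 282 in the highest other. For the restricted rhythm 1 of 100 gave as many as 116, with 81 in the highest other. A random order of the times is thus an unlikely source of the whole restricted count. The median of the other orders was 17 genes for the control and 24 for the restricted rhythm, so part of each count may be false calls. For the control rhythm a share of 4 in 100 orders lies too near 0.05 to decide.

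The first pattern was the set of diet calls that rested on replicate 2. RNA of ovary remnants may account for many of these calls. Of 2588 called genes outside the ovary list, 97.1% had, within the control libraries alone, the sign of slope on the ovary score that a lower score needs (77.6% of the genes not called). The share of calls is not settled, since 1 split of the diet labels with an ovary score difference of -1.96 called 721 genes. Less ovary tissue of unchanged makeup predicts equal changes of eggshell and germline genes. Within replicate 2 they changed by -3.86 and -1.98 on average, a difference of -1.88 (12 libraries per diet, permutation p = 0.0111). In replicate 1 that difference was -0.57 (permutation p = 0.341). The prediction was not borne out in replicate 2, but this does not exclude the explanation. Germline genes kept a mean of 3.15 log2 CPM in restricted replicate 2, against -0.49 for eggshell genes. Whether the kept tissue expresses them was not tested, and such expression would make their change smaller. Leaving out ribosomal RNA and mitochondrial rows decided nothing about the ribosomal RNA share of the libraries, since it moved little: of the 2642 genes called then, 2570 were among the 2601. Open are that share, less ovary tissue of unchanged makeup and an effect of the diet on egg production. A dissection that left other parts of the ovary, and changes in the fat body that go with egg production, are open too. The design does not separate these.

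The second pattern was the set of control rhythms lost with the marker scores. The count fell when the gut score was added to the ovary score, from 132 genes with the ovary score alone to 57 with both. No fit with the gut score alone was made. The median amplitude of the 84 lost genes outside the gut list fell from 2.58 (quartiles 0.54 and 3.85) to 0.91 (0.45 and 1.98). These genes were chosen for losing their call in that fit, so a fall was partly built in. A daily rhythm in the amount of gut RNA was not detected in the control libraries (permutation p = 0.347). The fitted curve of the gut score there had an amplitude of 1.05 and a peak at ZT 13.9, so such a rhythm is not excluded. RNA of gut remnants in single libraries stays open. Within restricted libraries 7.14% of the 84 correlated with the gut score at r above 0.5. Among the genes that kept their rhythm it was 0 of 48, and among all genes 3.12%. The share of 7.14% lay below the limit fixed beforehand as speaking against such RNA. It was still not taken to exclude it, since the highest gut score was 4.59 in restricted and 6.88 in control libraries. The prediction had not named that condition on the highest score. Without the control library of the highest gut score, ZT 14 of replicate 1, 78 genes passed, and no biological explanation was tested.

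The third pattern was the rise of the ribosomal RNA pseudogene rows on the restricted diet. A single library rich in ribosomal RNA is argued against as its cause, since without it 6 of the 6 named rows still passed, with a median log2 change of 1.21 against 1.49 with it. With both marker scores their calls ended at log2 changes of 1.34 to 1.66 with larger standard errors (edgeR adjusted p from 0.280 to 0.304). One pool of ribosomal RNA reads shared among near-identical rows is a candidate explanation for their joint behaviour, since their median pairwise correlation over control libraries was 0.996, so that the 6 rows may stand for 1 measurement. Whether carry-over of ribosomal RNA in library preparation or the diet raised that pool stays open, because nothing in the labels separates them.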

How the results depend on the processing

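The marker scores, the removal of ribosomal RNA and mitochondrial rows and the removal of the library rich in ribosomal RNA were chosen after seeing the data, as was holding the gene set fixed in the leave-one-out fits, and where no cause is given the cause was not tested. The diet count stayed within 1.5 times of 2601 under DESeq2, its size factors, no filter, no time term, the average of the 12 differences, the 20 most abundant genes left out, limma on log2(TPM + 1) and each library left out in turn (1810 to 2972, or 1766 to 2978 with the filter repeated). It ranged from 2 to 4334 within single replicate series, where the lone library of each time is assumed to vary like the others, and was 20 with the ovary score, 26 with both scores, 11 with both scores and a replicate block, and 554 at 1.5-fold. With limma on log2(TPM + 1) 309 genes were higher and 1599 lower (16.2% higher, against 40.3%), and the median of all genes moved by -0.10 on the log2 scale. The rhythm counts for control and restricted were 42 and 63 with limma on log2(TPM + 1), 58 and 57 with limma on log2 CPM, 25 and 45 for any shape over 12 times (which spends more degrees of freedom), 11 to 20 and 34 to 75 within single series, and 85 and 183 with both scores and the block. The control count was 57 with both scores and 78 to 186 with 1 library left out (81 to 194 with the filter repeated), and the restricted count 178 without the filter and 83 to 154 with 1 library left out (115 to 197 with the filter repeated). The rhythm difference of 2 became 15 without the filter, 14 with the replicate block, 7 with DESeq2, 16 with both scores, 23 with both scores and the block, 0 to 16 with 1 library left out (1 to 23 with the filter repeated), and 0 with limma on log2(TPM + 1) or log2 CPM, any shape, or a single series (143, 113, 134, and 331 to 373 at an unadjusted p under 0.05). The amplitude ratio of -0.05 became 0.15 to 0.22 within single series, 0.16 with limma on log2(TPM + 1), 0.19 with both scores, 0.22 with both scores and the block, and 0.16 over core clock genes, and was -0.21 to 0.08 with 1 library left out, while the phase shift of -0.21 h was -0.38 to 0.10 h with 1 library left out (-0.38 to 0.13 h with the filter repeated, where the highest moved by more than the SD of its permutations, 0.324 h). Over 32 lists camera called 13, and 0 with an estimated correlation, 14 with the block and 8 with both scores, of which 3 were among the 13 and 2 had the same direction. Lsp2 (-6.56 to 1.30) and Gnmt (-4.60 to 1.90) reversed between single series, with the positive values without replicate 2. Over the other settings of single genes 536 values kept their side of the threshold, 171 lost it and 7 gained it. Libraries of the same number correlated by -0.16 to 0.46 in their deviations from the group means, above 0.1 at 8 of 12 times. The numbers were therefore not taken to pair the libraries of each time, though the series differed in mitochondrial share in both diets. The replicate block gave 3824 diet calls, with 56 of 67 oxidative phosphorylation genes (13 without it), 9 of 21 glycolysis genes (3) and 11 of 14 hemocyte markers (3) higher, and rhythm counts of 151 and 171. In the simulation of the control rhythm 6.12% of amplitudes of 0.25 were recovered.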

Other observations

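The genes and the library left out in this part were chosen only after their values were seen, and no enrichment test was made. Genes of a further fatty acyl-CoA reductase, 2 fatty acid elongases and other enzymes cycled in both diets. The fatty acyl-CoA reductase gene CG10097 had amplitudes of 0.72 ± 0.14 and 0.99 ± 0.14 (SE, n = 24 libraries per diet) on the control and restricted diet, with peaks at ZT 3.90 and 3.09. The elongase genes CG18609 and CG17821 peaked in the dark phase, CG18609 at ZT 19.9 and 20.3 with amplitudes of 0.71 ± 0.14 and 0.74 ± 0.14, and CG17821 at ZT 21.5 and 21.1 with 1.42 ± 0.22 and 1.62 ± 0.22. Ugt36D1, a UDP-glycosyltransferase gene, reached 0.67 ± 0.08 and 0.88 ± 0.08 with a peak near ZT 3.4, GstZ2 0.68 ± 0.09 and 0.72 ± 0.09 near ZT 0.6 to 0.7, and Atg1 0.33 ± 0.06 and 0.35 ± 0.06 near ZT 23. The juvenile hormone esterase gene Jhe, at 1.35 CPM on average, had 1.26 ± 0.25 and 1.29 ± 0.25. All 7 passed in both diets (edgeR adjusted p from 1.8e-09 to 0.0233), in both diets also with the marker scores as covariates, and none differed between the diets (adjusted p = 1.00 for each).

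Antibacterial peptide genes were very high in a few libraries of the replicate 1 series. DptA had a median of 0.91 log2 CPM over 48 libraries and 9.66 in the control library of ZT 14, 7.96 at ZT 6 and 7.37 at ZT 10 of the same series, and 7.16 in the restricted library of ZT 2. AttC reached 9.42, 7.75, 7.31 and 7.86 in these libraries, against a median of 3.19, and Mtk 7.68, 6.32, 5.41 and 5.91 against 0.74. Libraries with DptA more than 4 log2 units above its median numbered 6, and 6 of these belonged to replicate 1. The control libraries of ZT 14 and ZT 10 in that series also had the 2 highest gut scores (6.88 and 4.87), and the restricted library of ZT 2 was the one with 53.8% ribosomal RNA. Of 40 humoral immunity genes 18 were rhythmic on the control diet and 12 differed in rhythm between the diets when adjusted over the list alone, and 0 over all genes tested for either (edgeR). Without the control library of ZT 14, replicate 1, these counts over the list alone were 2 and 0.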
